A study of Mus musculus with 18 samples.

How the data were processed

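RNA of stomach and intestine from normal, aging and high-dose codonopsis mice was measured on 18 one-colour Agilent arrays, with 3 arrays in each of 6 groups. The arrays were read with Feature Extraction 11.5.1.1 in the red channel alone, per the file headers, although the labels name the green dye Cy3. No spot was marked as saturated. The deposited intensity values are, per the file headers, spot signals after background subtraction and detrending by Feature Extraction, with low values replaced by a surrogate, and the median pixel intensity of each spot and its local background. Other deposited columns are, per the file headers, 0 or 1 marks for outliers, saturation and signal well above background. The series matrix holds log2 values by the authors, whose columns have a median of 5.33 on 17 arrays and 4.67 on codonopsis stomach replicate 2. How they were made is not given in the sources used here. They correlated with the scanner values of the same array at r of at least 0.999 with a slope between 0.991 and 1.09, which settles their log2 scale and direction, and they served as an alternative. The files name genome build mm9, so no coordinates are given, and names and neighbours come from a GRCm38.p6 gene table.

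The processed signal was averaged over the spots of a probe, without spots marked as outliers, and taken as log2 minus each array's 75th percentile. Because most probes were not well above background on the median array, a rule fixed in advance had the percentile run over 17378 probes well above background on all 18 arrays. A probe entered a fit if it was well above background on every array of at least 1 group in it. Where several probes matched a gene by accession, the brightest stood for it, and clone probes each stood for themselves. Features not well above background on any array of a group have only a bound there, the bright group's mean over, per array, the higher of the lowest signal well above background and the feature's own. No bound is given where it falls under 1-fold.

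Groups were compared with limma 3.58.1 in R 4.3.3, with 1 fit per tissue over its 9 arrays, sex as a term, and Benjamini-Hochberg adjustment at 0.05. Organs, and differences between organs, were compared in a fit over 18 arrays. Lists were tested with camera at a preset correlation of 0.01 and an estimated one. On simulated data, 14% of 100 stomach features changed by 1 on the log2 scale and 73% of 100 changed by 2 were called between codonopsis and aging among 30891 features, with 7 false calls. For the same intestine comparison the shares were 18% and 72% among 31367 features, with 3 false calls. The simulated data had independent noise for each feature, without an effect of slide, a mixture of tissues or correlation between features. These shares and false calls therefore need not hold for the real arrays. Tables were prepared with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and plots with matplotlib 3.10.9.

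The design, the alternatives and the rule for naming genes were set before the data were examined. The rule takes the 10 highest and 10 lowest log2 differences among features that passed without overlap of the groups' arrays, which chance gives in 10% of features for 3 against 3, and carry a gene symbol other than a clone or prediction name. It adds 2 noncoding features by ID each way and, where fewer than 5 passed in a direction, those with the smallest p up to 5. Most probes carry Agilent, NONCODE or clone identifiers without a gene name. Of 404 members of 23 pathway lists set in advance, 1 was tested, and 3 of 319 entries of 30 cell type lists, Synpo2 and Zg16, the last in the goblet and the pancreatic acinar list. Those lists could not be tested, and neither could sex-linked genes by name. Some items are withheld for evaluations, and results that need them are left out. In place of those lists 6 lists were drawn up from names the array carries, after values had been seen, and 4 had the 3 tested features needed in stomach and 3 in intestine. The X-linked regulators of dosage and the muscle-linked RNAs had too few in both, and the imprinted RNAs in intestine. A clone listed under a gene may measure another transcript of that locus.

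Several choices were changed after values had been seen. Clone probes whose clone is a synonym of a gene were first left unnamed and then counted as named. A first version filled values marked as outliers with the group mean, which gave some probes a spread near 0. Such values are now left missing, and a probe with one is not tested in that fit, which removes 201 probes in stomach and 249 in intestine. With filled values limma had called 0 features between aging and normal stomach, where 3110 now have an unadjusted p under 0.05, and 271 features had passed between codonopsis and aging stomach (6 of them filled) and 2378 between codonopsis and normal stomach (43 filled). In intestine 3, 3 and 7 had passed between aging and normal, codonopsis and aging, and codonopsis and normal mice, of which 1, 3 and 5 were filled. Of the probe sets, the intestine-high and stomach-high sets differ between the organs by 3 or more on the log2 scale on all aging arrays, and the further set was defined from codonopsis stomach replicates 1 and 2. All were defined after values had been seen. A wrong tissue label was first tested on the stomach-high probes, whose medians of −1.65 and −2.96 in codonopsis stomach replicates 1 and 2 (−2.93 in replicate 3), against −0.68 in normal and aging stomach and −6.40 in aging intestine, left replicate 2 undecided. The intestine-high probes replaced them after those values had been seen. The check of slide 1, and a fit over 18 arrays with a term for slide 1, were added last. That term is sized from 1 codonopsis intestine array against 2 and is taken to be the same in both tissues.

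Arrays lay 2 to 4 to a slide on 6 slides, each with 1 condition, so the comparisons of groups are confounded with slide in both tissues. In stomach all codonopsis arrays lie on slide 1. The aging intestine arrays lie on slide 4 and the normal intestine arrays on slide 6. In intestine codonopsis lies on 2 slides, with replicate 1 on slide 1 and replicates 2 and 3 on slide 2, which allows a check of slide 1 there. Slide 1 held the 3 codonopsis stomach arrays and 1 codonopsis intestine array, and slide 6 held 1 normal stomach and 3 normal intestine arrays. Replicate numbers follow the order of the samples. Alternatives to scaling, background, filters, weights, blocks, sex term and replicates were computed, as were the authors' log2 values. The alternative for cell type marker levels and those for lists set in advance were not run for want of named members.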

Results

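Gene expression was measured in the stomach and the intestine of Kunming mice, an outbred strain, at 2 months of age. The series title places the study in the D-galactose model, in which repeated doses of this sugar are given to produce changes that resemble aging. It asks how Codonopsis pilosula, a root used in herbal medicine, alters the RNA profile of the digestive tract in that model. Each tissue had 3 groups, labelled normal, aging and high-dose codonopsis, with 3 arrays per group and 18 arrays in all. Stomach groups each held 1 male and 2 females, the normal and codonopsis intestine groups each held 2 males and 1 female, and the aging intestine group held 3 females. The labels say that donors differed between replicates, so the spread within a group was taken as the spread between mice.

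Each array carried 97836 non-control probes for noncoding and coding transcripts. A gene name could be given to 4658 of them by accession and to 1210 by the gene that lists their clone as a synonym, so most differences have no gene. The share of spots well above background lay between 31.4% and 39.7% on the 9 intestine arrays and between 31.9% and 40.6% on the normal and aging stomach arrays. It was 23.5%, 21.9% and 30.1% on the 3 codonopsis stomach arrays. Within a group, arrays correlated with r between 0.897 and 0.976 across probes, lowest in codonopsis stomach.

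Between codonopsis and normal stomach most called features also moved in the 1 codonopsis intestine array that shares a slide with the codonopsis stomach arrays, so they are not separated from slide. Slide 1 holds the 3 codonopsis stomach arrays and codonopsis intestine replicate 1, and codonopsis intestine replicates 2 and 3 lie on slide 2. Of 1905 called features tested in intestine, 92.1% had the same sign in replicate 1 minus replicates 2 and 3, against 9.34% to 71.1% when each of the other 8 intestine arrays was set against its own group. The lowest share is that of codonopsis replicate 3, whose reference includes the slide 1 array, and aging and normal arrays gave 31.8% to 71.1%. Over all features tested in both tissues 66.4% had the same sign in replicate 1. With a term for slide 1 in a fit over 18 arrays, added after the values were seen, limma called 1 feature (2688 at an unadjusted p under 0.05), against 5852 in the same fit without the term and 2306 in the fit of the 9 stomach arrays, of which it was not 1. The median size of the called differences went from 1.25 to 0.64 on the log2 scale, and the median SE of all features from 0.24 to 0.45.

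Snhg3, a host gene of small nucleolar RNAs, was 3.16-fold higher in codonopsis than in normal stomach (log2 difference 1.66 ± 0.27, SE, n = 3 against 3; limma adjusted p = 0.0198), with a scaled log2 signal of −2.62 ± 0.28 (SD) against −4.28 ± 0.17. In codonopsis intestine it had −3.63 on slide 1 against −3.57 and −3.46 on slide 2, and with the slide term its difference was 1.68 ± 0.47, which did not pass. Snhg3 also differed by 1.17 ± 0.27 between aging and normal stomach and by 0.49 ± 0.27 between codonopsis and aging stomach. Neither of these passed, and neither is separated from slide. Kis2, a noncoding RNA, was 3.07-fold higher in codonopsis stomach (1.62 ± 0.33; limma adjusted p = 0.0295), and also higher on slide 1 in intestine (2.04 against 1.18 and 1.57). One clone listed under Bclaf1, a gene named for binding BCL2 family proteins, was 3.59-fold higher, with −1.30 on slide 1 against −1.97 and −1.66 in intestine, while the other Bclaf1 clone differed by 0.18 and did not pass. The pseudogene Selenok-ps1 was 2.26-fold higher and the Kalrn clone 2.09-fold higher, and with the slide term they differed by −0.10 ± 0.35 and 0.16 ± 0.36. For Fads2, the delta-6 fatty acid desaturase gene, the clone was 1.72-fold higher, with 2 of 3 codonopsis arrays well above background, and 0.30 ± 0.40 with the slide term.

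Among the transcripts lower in codonopsis than in normal stomach, those with a lower signal on slide 1 in intestine include the clone listed under Dnal1, an axonemal dynein light chain. It differed by −1.43 ± 0.27 in stomach (SE; limma adjusted p = 0.0248) and had −0.96 on slide 1 against 0.74 and 1.36 on slide 2 in codonopsis intestine, and 0.27 ± 0.46 with the slide term. The clone listed under Rpgrip1, a protein of the photoreceptor cilium, differed by −1.39 ± 0.24 (limma adjusted p = 0.0216), with −1.01 against 0.44 and 1.14 in intestine and 0.07 ± 0.39 with the slide term. The clone listed under Bora, an activator of Aurora A kinase, differed by −1.23 ± 0.26, with 2 of 3 codonopsis arrays well above background, and by −0.17 ± 0.39 with the slide term. Hnf4aos, the antisense RNA of the endoderm factor gene Hnf4a, was at least 1.49-fold lower in stomach and had −4.51 on slide 1 against −3.36 and −2.68 in codonopsis intestine, and a clone also listed under Hnf4aos differed by −0.59 without it and did not pass. The noncoding Gm34128 was at least 3.09-fold lower in stomach, and had −6.26 on slide 1 against −1.90 and −1.58 in codonopsis intestine. The Nwd2 clone was at least 1.21-fold lower, with −4.99 against −3.78 and −3.20. The clones listed under Scrn1 and Lamb1, the second for a laminin chain, also passed, were too dim in codonopsis stomach for a bound, and lay lower on slide 1 in intestine too.

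Other transcripts lower in codonopsis stomach had a slide 1 value in intestine between those of slide 2. Trim52, a tripartite motif gene, differed by −1.88 ± 0.48 in stomach (SE; limma adjusted p = 0.0489), with −1.36 and −0.04 on slide 2 around −1.25 on slide 1. The pseudogene Speer5-ps1 was at least 2.09-fold lower and Chchd7, a mitochondrial protein gene, at least 2.06-fold lower, both below background on every codonopsis stomach array. With the slide term Trim52 differed by −2.08 ± 0.87 and did not pass. Of the 21 features named or given by ID in the tables of this comparison, 15 had a slide 1 value beyond both slide 2 values in the direction of the stomach difference.

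The clone listed under Zg16, a lectin of goblet cell mucus and of pancreatic zymogen granules, was the named feature with the highest difference in both stomach comparisons with codonopsis. Its scaled log2 signal was 4.21 and 3.80 in codonopsis stomach replicates 1 and 2 and −2.17 in replicate 3, against −5.04 ± 2.03 (SD, n = 3) in normal stomach, where 1 of 3 arrays lay well above background. The difference from normal was 6.98 ± 1.30 (SE; limma adjusted p = 0.0248), and the intestine arrays lay between 2.04 and 3.37, with 2.04 on slide 1 against 2.39 and 2.07 in codonopsis intestine. Replicates 1 and 2 were also the arrays in which 553 intestine-high probes, those at least 8-fold brighter on every aging intestine array than on every aging stomach array, lay higher than in normal and aging stomach, by a median of 2.74 and 1.15 on the log2 scale. In replicate 3 that median was −0.11. A further set of 58 probes was picked for being over 8-fold brighter in the same 2 arrays than in every other stomach array, and dim in the median intestine array. Its rises of 5.32 and 5.10 in the 2 arrays follow from that choice. The Zg16 clone there exceeded every intestine array, of which the 2 brightest, normal replicate 3 and aging replicate 2 at 3.26 and 3.37, also carry the further set. Both organ sets were defined after values had been seen, and their shifts in codonopsis stomach are not separated from slide 1. The 161 intestine-high probes tested in stomach differed between codonopsis and normal by a median of 0.91 (camera p = 1.82e-14, and p = 0.2455 with an estimated correlation). The 110 stomach-high probes, defined the opposite way, differed there by a median of −1.06 (camera p = 3.68e-10, and p = 0.0116 with an estimated correlation). Their median signal was −1.65, −2.96 and −2.93 in codonopsis replicates 1, 2 and 3, against −0.68 in normal and aging stomach, so it was low in replicate 3 as well, where intestine-high probes were not raised.

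**Figure D1:**
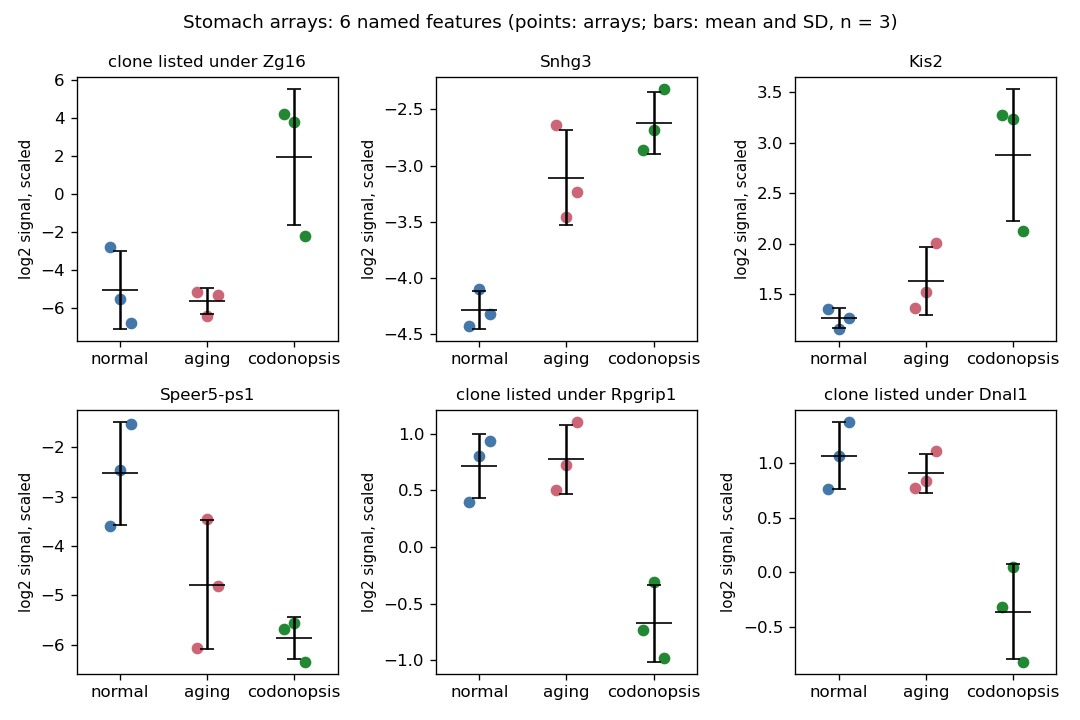
Scaled log2 signal of 6 named features on the 9 stomach arrays, by group; points are arrays and bars the mean and SD of 3 arrays. The Zg16 clone reaches 4.21 and 3.80 in 2 codonopsis arrays and −2.17 in the other, while the Dnal1 clone lies between −0.82 and 0.05 in codonopsis and between 0.76 and 1.37 in normal stomach.

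**Figure D2:**
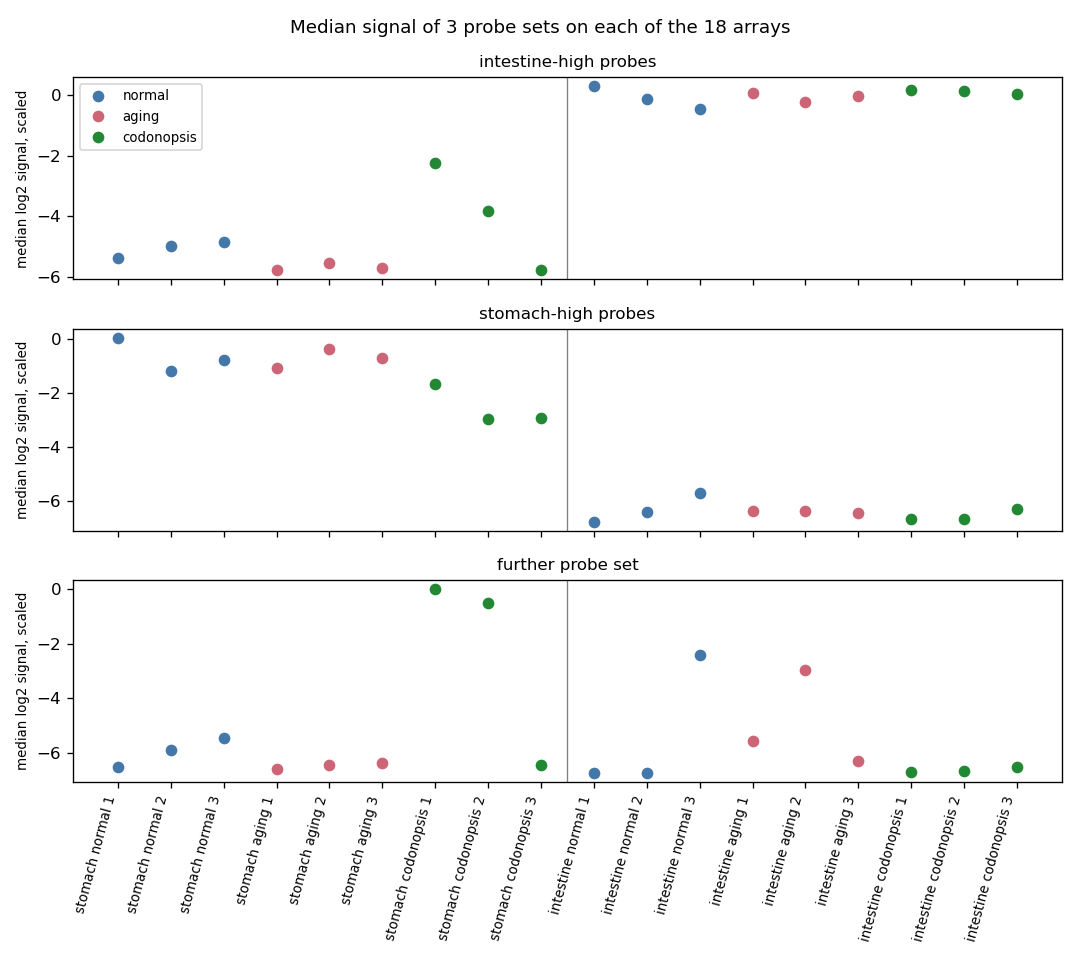
Median scaled log2 signal of 553 intestine-high probes, 110 stomach-high probes and a further set of 58 probes on each of the 18 arrays, coloured by condition. Intestine-high probes reach −2.24 and −3.80 in codonopsis stomach replicates 1 and 2, against −5.75 in replicate 3.

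Across the 30891 features tested in stomach, 2306 differed between codonopsis and normal mice by limma at an adjusted p under 0.05, 609 of them higher and 1697 lower in codonopsis, before any term for slide. Of the 233 features with a gene name, 7 were called higher and 20 lower. The share of higher calls was 26.4% here, 49.4% when arrays were scaled on all probes, 41.4% after quantile normalization and 58.9% with normexp background, so the preponderance of lower calls rests on the scaling and background choice. The count also rests on single arrays: it was 2 without normal replicate 2, 95 without codonopsis replicate 2, 157 without normal replicate 3, 943 and 1226 without aging replicates 2 and 3, 1245 without normal replicate 1, and 3487 without codonopsis replicate 3.

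Codonopsis stomach set against aging stomach gave many of the features already named, and most of these moved with slide 1. Of 231 called features tested in intestine 94.8% had the same sign in codonopsis replicate 1 minus replicates 2 and 3, against 6.49% to 58.9% for the other 8 intestine arrays and 34.2% to 58.9% for the aging and normal ones. Over all features tested in both tissues 66.1% had the same sign in codonopsis replicate 1. With the slide term limma called 1 feature (1329 at an unadjusted p under 0.05), against 1026 in the same fit over 18 arrays without it, and the median size of the called differences went from 1.54 to −0.0046. The Zg16 clone was at least 83.8-fold higher (limma adjusted p = 0.0410), being below background on all 3 aging arrays. The Rpgrip1 clone differed by −1.45 ± 0.24 (SE; limma adjusted p = 0.0357), with −0.68 ± 0.34 against 0.78 ± 0.30 (SD, n = 3 each), and by 0.0073 ± 0.39 with the slide term. The clones of Lamb1 and Scrn1, again below background in codonopsis stomach, and the noncoding Gm34128 also passed, and all 3 lay lower on slide 1 in intestine. Of the 8 passing features named or given by ID in the tables, 6 had a slide 1 value beyond both slide 2 values in the direction of the stomach difference. The others were the Zg16 clone and the clone C330004M20, which differed by 1.82 ± 0.32 (limma adjusted p = 0.0416), had −0.25 on slide 1 against 0.73 and 0.74 in codonopsis intestine, and differed by 3.09 ± 0.74 with the slide term, which did not pass. Among features that did not pass, Selenok-ps1 differed by 1.11 ± 0.22, the Kalrn clone by 0.96 ± 0.21, the Fads2 clone by 0.95 ± 0.20 and the Bora clone by −1.28 ± 0.26. Without the slide term 254 features passed, 58 higher and 196 lower. Of these, 50 higher and 185 lower features were also called in the same direction against normal stomach, where independent lists would share 1.14 and 10.8; both comparisons use the same codonopsis arrays, which raises the overlap by itself. The count rests on single arrays: 0 features passed limma without aging replicate 2 or without aging replicate 3, 31 without normal replicate 3, 36 without normal replicate 1 or 2, 55 and 112 without codonopsis replicates 2 and 1, 550 without aging replicate 1 and 1926 without codonopsis replicate 3. The first 2 counts of 0 stand beside 5436 features at an unadjusted p under 0.05 with all arrays. The share of higher calls was 22.8% here and 41.1% with normexp background.

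Aging stomach differed from normal stomach by limma in 1 of 30891 features, the unnamed probe A_55_P1973352, which rose by 3.02 ± 0.28 (SE) to 2.78 from −0.24 and is named here after its value was seen. At an unadjusted p under 0.05 there were 3110 features, 10.1% of those tested. Among named features that did not pass, Snhg3 differed by 1.17 ± 0.27, Snhg8 by 0.60 ± 0.21 and Snhg5 by 0.74 ± 0.33, all hosts of small nucleolar RNAs. The Dusp4 clone, listed under a phosphatase gene of the MAP kinase pathway, was above background in aging stomach and in none of the normal arrays, at least 1.76-fold brighter with an adjusted p of 0.352. Speer5-ps1 differed by −2.26 ± 0.54, Pla2g10os by −1.29 ± 0.34 and the Wdr70 clone by −0.82 ± 0.23. Limma called 0 features without any one of the 3 aging arrays, without normal replicate 1 or without codonopsis replicate 1, and 0 with normexp background. Without normal replicate 2 another feature passed instead, 2 passed without codonopsis replicate 3 and 49 without normal replicate 3.

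Named features of the intestine did not pass in any comparison of groups. Each slide holds a single condition, so differences between intestine groups are not separated from slide. All 3 aging intestine mice were female, so the sex term, which rests on the other groups, changes the sizes of the differences from aging mice, and the values without it follow those with it. Of those nearest to passing between aging and normal mice, the clone listed under Slc23a4, a member of the ascorbate transporter family, differed by 1.18 ± 0.22 (SE; limma adjusted p = 0.0771; 0.71 without the term) and the Arhgef5 clone by 1.14 ± 0.22 (0.84). Carmn, a noncoding RNA of muscle cells, differed by 1.16 ± 0.26 (0.93) between aging and normal mice and by −1.11 ± 0.26 (−0.87) between codonopsis and aging mice. Nrg3os differed by −1.48 ± 0.27 (−0.67) and Speer4cos by −1.82 ± 0.36 (−0.93) between aging and normal mice. The Abhd17b clone differed by −0.86 ± 0.20 (−0.43) between aging and normal mice and by 0.88 ± 0.20 (0.45) between codonopsis and aging mice. Between codonopsis and normal mice the Slc23a4 clone differed by 0.90 ± 0.18 and the pseudogene Marcksl1-ps4 by 1.03 ± 0.26.

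Of 31367 intestine features, 2 unnamed probes, A_55_P1967643 and A_52_P311519, fell in aging and in codonopsis intestine against normal intestine, and they are named here after their values were seen. Their scaled log2 signals were −1.04 ± 0.69 and 0.58 ± 0.62 (SD, n = 3) in normal intestine, and no aging or codonopsis array lay above −6.14 for the first or above −4.07 for the second. The normal intestine arrays all lie on slide 6, which holds no aging or codonopsis array, so these falls are not separated from slide. Limma called 0 features between codonopsis and aging intestine, with 2966 at an unadjusted p under 0.05, against 5178 between aging and normal and 3043 between codonopsis and normal intestine. Without normal replicate 1, 1537 features passed between aging and normal intestine, 26 without codonopsis replicate 2, 6 without aging replicate 2, 5 without codonopsis replicate 1, and 1 without normal replicate 2 or aging replicate 3. Between codonopsis and aging intestine 9 passed without codonopsis replicate 1, 5 without aging replicate 2 and 2 without normal replicate 3, and between codonopsis and normal intestine 7 passed without normal replicate 2 and 4 without normal replicate 1.

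Whether codonopsis moved transcripts against the direction of aging was read from the correlation across features of aging minus normal with codonopsis minus aging. Both differences use the aging arrays, so chance alone gives a negative value. In stomach r was −0.0933, against −0.501 in data simulated without group effects, and the covariance was −0.0237 against −0.0680. With single arrays left out, the stomach r ranged from −0.283 to 0.0810, turning positive without codonopsis replicate 1. In intestine r was −0.684 against a simulated −0.665, and the covariance was −0.140 against −0.0777. For aging minus normal with codonopsis minus normal, which share the normal arrays, the covariance was 0.179 against 0.0684 in stomach and 0.0963 against 0.0395 in intestine. Features are not independent replicates and no p is attached. The stomach values use the codonopsis arrays of slide 1, and each slide holds a single condition, so the values of neither tissue are separated from slide.

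The organs differed widely. Btnl5-ps, a pseudogene next to the butyrophilin-like gene Btnl4, was higher in intestine (9 against 9 arrays; limma adjusted p = 1.81e-07), with 1 of 9 stomach arrays well above background and the brightest, codonopsis replicate 1, at −1.91, and the clone listed under Mcu, the mitochondrial calcium uniporter, was 4.29-fold higher. Clca4c-ps was at least 9.14-fold higher, Cyp2d13, a pseudogene of the cytochrome P450 family, at least 7.61-fold higher and the clone listed under A1cf, a cofactor of apolipoprotein B RNA editing, at least 4.16-fold higher. The Slc23a4 clone was at least 3.18-fold higher and Slc22a13b at least 3.29-fold higher. In stomach the Eml1 clone was higher (intestine minus stomach −2.81 ± 0.24), and Synpo2, the gene of an actin-binding protein of muscle, was at least 2.87-fold higher by one clone and differed by −1.07 ± 0.15, intestine minus stomach, by the other. The imprinted RNA Rian was at least 1.30-fold higher in stomach. By limma 16341 of 34528 features differed, 7698 higher and 8643 lower in intestine, among them 84 and 53 named features. The 2 slides that hold both organs, slides 1 and 6, have a single array of one of them. Within slides 1 and 6 the organ differences correlated with those of all arrays at r 0.884 and 0.902. Of the features called between the organs, 95.7% and 91.0% had the same sign there. Each of these values rests on that single array, and the arrays of the slide are also among all arrays.

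Across both tissues 4 probes were brighter in every female array than in every male array by over 2 on the log2 scale, and 2 were brighter in every male array. Probe A_52_P300376 had a scaled log2 signal of 1.18 ± 0.53 (SD) in the 11 females and −6.60 ± 0.42 in the 7 males, none of which lay above background. NONMMUT074748 had −2.45 ± 0.44 in males and −6.60 ± 0.37 in females, with no female above background. Neither carries a gene name here. By limma 1 feature in stomach and 10 in intestine differed between sexes, 2 of the 10 higher in males. A probe is tested only if well above background on every array of a group, and every stomach group holds both sexes, so probes seen in 1 sex alone are left out there. In intestine those seen in females alone enter through the all-female aging group. No intestine group is all male, so those seen in males alone are left out in both tissues, which lowers the counts higher in males. Without that filter 107 and 30 features passed. The stomach count was 95 without aging replicate 1, 5 without normal replicate 1 and 4 without codonopsis replicate 1. The intestine count was 229, 69 and 16 without normal replicates 2, 1 and 3, and 21 and 26 without codonopsis replicates 2 and 3.

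Small groups of noncoding RNAs were picked from the names the array carries after values had been seen, so the p of these groups are not independent evidence. Between aging and normal stomach 3 of 6 snoRNA host genes were positive and 3 negative, with a median of 0.30 on the log2 scale. The positive ones, Snhg3, Snhg5 and Snhg8, had already been among the features nearest to passing in that comparison. Camera gave an adjusted p of 0.0238 with a preset correlation of 0.01 and 0.149 with an estimated one. No member passed over all features, and 1 of 6, Snhg3, passed when adjusted over the list alone. Gata6os and Hnf4aos, antisense RNAs of endoderm transcription factor genes measured by 3 features, lay lower in codonopsis than in normal stomach, with a median of −1.13 and a camera adjusted p of 0.0438, which became an adjusted p of 0.301 with an estimated correlation. There 1 of the 3 features, of Hnf4aos, passed over all features and 3 when adjusted over the list alone, and that feature of Hnf4aos lay lower on slide 1 in intestine. Camera called neither the imprinted RNAs nor the RNAs linked to p53 and genome stability in any comparison of groups.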

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

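In this part the tests of intestinal tissue, wrong labels, dim arrays, a shared response, a trait of the mouse, carry-over, scaling, background and slide were chosen after the results were seen; the correlation within the further probe set, the replicate 3 check and the splits were set beforehand.

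The interaction test asked whether a difference between groups differs between intestine and stomach. For aging against normal 3 features passed, the probes A_55_P1967643 and A_52_P311519, well above background in normal intestine alone, and the clone A530099A19, which was below background on every stomach array, so their fitted values (intestine minus stomach, log2) of −5.09, −4.83 and 4.14 rest on signal at the floor and are not sizes. The clone A530099A19 had −0.71, −0.91 and −0.83 in aging intestine and −3.11, −2.85 and −3.97 in normal intestine, and lay between −6.73 and −5.15 in stomach. For codonopsis against aging 1 feature passed, A_55_P1995350, fitted at −5.13 with 1 group at the floor, with −0.25, −2.02 and −2.33 in codonopsis stomach, −5.94 or less, below background, in the other stomach arrays and 1.27 to 2.34 in intestine. For codonopsis against normal 4 features passed, among them A_55_P1967643 and A_52_P311519, whose fitted values of −5.81 and −5.82 again rest on signal at the floor. Another, A_52_P570266, lay above the floor, with 0.42, 0.25 and 0.02 in codonopsis stomach and −2.44 to −1.79 in the other stomach arrays. In codonopsis intestine it had −0.18 on slide 1 against −0.17 and −0.38 on slide 2. In splits within tissues as many features passed in 13, 29 and 7 of 100, with up to 858, 559 and 4270, so chance is not excluded for any of the 3 counts. Splits with several times the real count point to a structure of the samples.

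Single arrays move these counts. For aging against normal, 0 features passed limma without intestine normal replicate 3 (1192 at an unadjusted p under 0.05 with all arrays), 5 without intestine aging replicate 2 and 52 without stomach normal replicate 3. For codonopsis against aging, 0 passed limma (4557 at an unadjusted p under 0.05 with all arrays) without stomach aging replicate 2 or 3, intestine aging replicate 3, or any one intestine normal array. There 2 passed without stomach codonopsis replicate 2, intestine codonopsis replicate 2 or 3, or intestine aging replicate 1, and 3 without intestine aging replicate 2. Further values were 5 without stomach normal replicate 2, 200 without intestine codonopsis replicate 1, 298 without stomach aging replicate 1 and 452 without stomach codonopsis replicate 3. For codonopsis against normal, 2 passed without intestine codonopsis replicate 3, intestine normal replicate 2 or intestine normal replicate 3. The count there was 7 without stomach aging replicate 3, 25 without stomach codonopsis replicate 1, 68 without stomach normal replicate 3, 72 without stomach aging replicate 1, 286 without intestine codonopsis replicate 1 and 1122 without stomach codonopsis replicate 3.

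Codonopsis stomach replicates 1 and 2 carry transcripts that are bright in intestine. An intestine sample under a wrong label is argued against. The median of the intestine-high probes was −2.24 and −3.80 there and −0.46 or more on every intestine array. A response shared by all 3 treated mice is argued against too, since the median rise in replicate 3 was −0.11. Dim arrays are argued against for replicate 1, where the median rise was 2.74. For replicate 2 the rise of 1.15 cannot decide this, because scaling lifts the floor of a dim array. Slc22a13b, below background on every stomach array, had −5.69 and −5.55 in replicates 1 and 2. It lay between −6.89 and −6.53 in normal and aging stomach. Intestinal tissue in the samples stays open: 71.1% and 31.8% of these probes lay at least 2-fold above the brightest normal or aging stomach array in replicates 1 and 2, where over 90% had been set as the mark of that explanation. An earlier criterion, that under 50% would exclude it, was met by replicate 2, and was replaced after that value was seen, because the median implied share of intestinal RNA, 4.0% there and 18% in replicate 1, would itself lift only 23.9% and 81.2% of the probes that far. A response in some treated mice was not tested and may also account for it.

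A further 58 probes, 55 of them without a gene name, were picked for being bright in codonopsis stomach replicates 1 and 2 and dim in the other stomach arrays. Of these probes, 96.6% had normal intestine replicate 3 and aging intestine replicate 2 as the 2 brightest of the 9 intestine arrays. For a trait of the mouse, the other-tissue arrays that share the title codes had a highest median rise of 0. Those in stomach were kept dim by the choice of the set, so they cannot decide this. Codonopsis intestine replicate 2 alone was free to rise, and its median rise was −0.22. It speaks to codonopsis stomach replicate 1 only, if a shared code marks a mouse, so a trait of the mouse stays open. For carry-over on a slide, the intestine arrays among the 7 other arrays of those slides had a highest median rise of 0.32. The set was also kept dim in the median intestine array, and the rise was measured from that median. A rise shared by most intestine arrays was thus kept out by the choice of the set. The value argues only against carry-over to a single intestine array, and carry-over otherwise stays open. The stomach arrays among the 7 were kept dim by the choice of the set. The rises in codonopsis stomach replicate 1 and normal intestine replicate 3 correlated across the probes with r 0.748, so 1 further tissue carried in 4 of the samples may be their source. Which tissue that would be was not tested, and no biological explanation was tested.

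The features called in codonopsis stomach, most of them lower, moved in the same direction in codonopsis intestine replicate 1, the 1 intestine array on their slide, set against replicates 2 and 3 on another: 92.1% of those called against normal stomach and 94.8% of those called against aging stomach, with at most 71.1% and 58.9% for any other intestine array. Over all features tested in both tissues that array gave 66.4% and 66.1%. An effect of slide 1 may therefore account for most of the calls against aging stomach, whose median size was −0.0046 with the slide term. How much of the calls against normal it accounts for stays open. With the term 81.6% of 2298 such features kept their sign, with a median size of 0.64 against 1.25 without it. All of this rests on 1 intestine array, and that array's mouse shares no title code with the stomach arrays. Scaling may account for the preponderance of lower calls against normal, since 49.4% were higher with scaling on all probes. Among features well above background on every stomach array 51.6% were higher. That filter drops features for being dim in codonopsis stomach, such as Gm34128 and Hnf4aos, so it cannot decide whether signal near background accounts for it. Intestinal tissue in replicates 1 and 2 as the whole cause of the calls against normal is argued against: it moves features toward their intestine level, and 52.7% of the 2302 such calls without missing values had the sign of aging intestine minus aging stomach, against 52.8% of all features, where at least 90% had been set as the mark of that explanation and at most 75% as the mark against it. Without the intestine-high, stomach-high and further-set probes 2479 features passed, 2283 of them shared with the 2306. Those sets hold 161, 110 and 9 of the 30891 features tested in stomach. Their removal could take away few calls, so this count cannot decide whether added tissue accounts for the rest. A mixture with another tissue as the whole cause stays open: of 978 features called from replicates 1 and 2 of both groups, 70.4% had the same sign in replicate 3 (64.9% of the higher and 76.9% of the lower), between the bounds of 60% and 80% set beforehand, and 57.6% over all features. A response to codonopsis stays open.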

How the results depend on the processing

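In this part the tests with a slide 1 term, those without the 4 arrays that carry intestine-high or further-set probes, and those without these probes, were chosen after the results were seen; all other alternatives were planned. The count of features between the organs kept within 1.5 times of 16341 under every alternative but the 2 filters. Of the named genes and features, those between the organs kept direction and side of the threshold in 747 of 747 comparisons with an alternative. Between codonopsis and normal stomach this held in 407 of 555, with 140 losing the threshold and 8 turning. Between codonopsis and aging stomach it held in 233 of 368, with 87 losing the threshold, 39 passing it and 9 turning. Signal over background limits the dim features: the turns that did not come with the slide 1 term came under the floor at the lowest signal well above background, which lies above those signals by construction. Except where the text names it, the cause of a change was not tested. The alternatives for cell type marker levels and for lists set in advance were not run. Scaling and background moved the median log2 difference of all tested features: for codonopsis minus normal stomach it was −0.09 in the chosen scaling and 0.09 with scaling on all probes, and for aging minus normal stomach −0.08 and 0.11. For codonopsis minus aging stomach it was −0.01, 0.11 with normexp background and 0.15 with the floor.

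Counts moved over 1.5 times follow, against 1, 254 and 2306 in stomach for aging against normal, codonopsis against aging and codonopsis against normal, and 2, 0 and 2 in intestine (limma; 2966 at an unadjusted p under 0.05 for the 0).

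With quantile normalization codonopsis against aging stomach gave 408 and aging against normal intestine 1; with the percentile over all probes 444 and 54; with the authors' log2 values the first gave 388. Normexp background gave 0, 56 and 851 in stomach, 0 for the interaction of codonopsis against aging and 1 list shift instead of 2. Without the filter on dim probes 21666 passed between codonopsis and normal stomach, 107 for sex in stomach and 30 in intestine, 1 each for aging and codonopsis against normal intestine, 41611 between the organs and 2 for the interaction of codonopsis against aging. With probes well above background on every array 140 and 1032 passed for codonopsis against aging and normal stomach and 7452 between the organs, with fewer features tested. There 0 passed for sex in stomach, 0 for aging and for codonopsis against normal intestine, 1 for sex in intestine, and 0, 0 and 1 for the interactions of aging against normal, codonopsis against aging and codonopsis against normal. The intestine correlation was −0.738.

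With the floor 2, 67 and 494 passed in stomach, 6 between aging and normal intestine, 1 between codonopsis and aging intestine, 6 for sex in intestine and 2 for the interaction of codonopsis against aging. Under it, codonopsis minus aging stomach turned to 0.15 for the Lamb1 clone, 0.83 for Scrn1 and 0.24 for Zim3, and codonopsis minus normal stomach to 0.059 for Lamb1 and 0.24 for Scrn1.

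With a slide 1 term in a fit over 18 arrays, 20, 1 and 1 passed in stomach, with 0 of the 254 and of the 2306 among them, 4 between aging and normal intestine, and 0 and 2 for the interactions of codonopsis against aging and against normal. That term's SE is wide and its size comes from codonopsis intestine. There slide 1 minus slide 2 was −4.52 for Gm34128 and −1.49 for Hnf4aos, against stomach differences from normal of −3.58 and −1.28. Scrn1, Gm34128, NONMMUT007394 and Hnf4aos are not well above background on any codonopsis stomach array, so their fitted values are not sizes. Brighter features such as Rpgrip1 and Dnal1 turned as well, so the turned signs are not put down to dim signal. Under it codonopsis minus aging stomach turned for Selenok-ps1 (−0.16), Rpgrip1 (0.0073), Scrn1 (1.15), Gm34128 (0.92), NONMMUT072927 (−0.21) and NONMMUT007394 (1.26). Codonopsis minus normal stomach turned for Selenok-ps1 (−0.10), Scrn1 (0.52), Dnal1 (0.27), Rpgrip1 (0.069), Hnf4aos (0.014) and Gm34128 (0.87).

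Array weights gave 339, 12142 and 16572 in stomach, 482 and 6 in intestine for aging against normal and codonopsis against aging, 586 for sex in intestine, and 6, 6737 and 10386 for the 3 interactions; the weights of at least 1 of these fits stopped before the convergence tolerance. With slide as a random block 646, 8322 and 9350 passed in stomach; the block correlation was −0.286 and each slide holds 1 condition, so these counts carry little weight. Title code as a block gave 5 for the interaction of aging against normal. Without the sex term 385 passed between codonopsis and aging stomach, 9 in intestine and 2 for their interaction, and the intestine correlation was −0.562. With females alone 0 passed between aging and normal stomach and 3667 between codonopsis and normal stomach. There 1661 passed between aging and normal intestine and 0 between codonopsis and normal intestine, where 1 normal and 1 codonopsis female stand alone and are assumed to vary like the others.

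A fit with a replicate block gave 31 between codonopsis and aging stomach, 512 between codonopsis and normal stomach and 0 between aging and normal intestine. The labels share only a number: same-numbered arrays had deviations correlating from −0.350 to 0.240 in stomach and −0.312 to 0.323 in intestine, over 0.1 in 3 and 2 of 9 pairs.

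An unadjusted p under 0.05 with at least 2-fold gave 1089 and 1575 for aging against normal and codonopsis against aging stomach and 1199, 632 and 232 in intestine. A fit over 18 arrays gave 20, 1026 and 5852 in stomach, 5 and 2 for aging against normal and codonopsis against aging in intestine, and 1 list shift. With an estimated correlation camera called 0 lists, against 2, which had preset p of 0.0238 and 0.0438 and estimated p of 0.149 and 0.301. Without codonopsis stomach replicates 1 and 2, 4222 passed between codonopsis and normal stomach, the lone replicate assumed to vary like the others. Between codonopsis and aging stomach 254 passed again, but 89 of them were shared. Without normal intestine replicate 3 and aging intestine replicate 2, 4 passed between aging and normal intestine and 7 between codonopsis and aging intestine.

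Leaving out 1 array at a time gave 0 to 49, 0 to 1926 and 2 to 3487 in stomach and 1 to 95 for sex there, 1 to 1537, 0 to 9 and 2 to 7 in intestine and 9 to 229 for sex there, and 14491 to 18256 between the organs. The interactions of aging against normal, codonopsis against aging and codonopsis against normal ranged from 0 to 52, 0 to 452 and 2 to 1122. The correlation across features ranged from −0.283 to 0.0810 in stomach, turning without codonopsis replicate 1, and from −0.774 to −0.599 in intestine.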

Other observations

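In this part the tests of title codes were chosen after the result was seen, and the splits were set beforehand.

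Beyond the genes named so far, stomach and intestine differed in several noncoding and clone-derived transcripts. Lncpint, a noncoding RNA linked to p53, was lower in intestine (intestine minus stomach −1.17 ± 0.15, SE, 9 against 9 arrays; limma adjusted p = 1.38e-05), and the clone listed under Lrrn1 differed by −2.56 ± 0.39 (limma adjusted p = 8.36e-05). Mir100hg, a host of microRNAs, was at least 1.84-fold higher in stomach by its clone, and the clone listed under Chd2, a chromatin remodeller, at least 4.90-fold higher. For Dennd5b the clone was at least 4.12-fold higher in intestine. On the Zg16 clone the scaled log2 signal was 3.26 in normal intestine replicate 3 and 3.37 in aging intestine replicate 2, against 2.04 to 2.46 on the other 7 intestine arrays.

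Some title codes occur in both tissues, and the hypothesis that a shared code marks a shared mouse was tested. Across 27275 features the deviations from the group mean correlated with a mean r of 0.206 in 5 same-code pairs, between 0.105 and 0.327, and −0.0458 in other pairs of the same condition, of which the highest reached 0.351 (exact one-sided p = 0.00583 over 2916 placements). A shared mouse may account for this. Arrays of the same code also share a sex, while other pairs can mix the sexes. Neither sex nor a shared handling of the samples was tested as the source. A first version on 3 probes that are bright in some arrays and dark in others had given an exact permutation p of 0.000686, but 2 of those probes had prompted the hypothesis, so that p is not independent evidence.

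With 3 against 3 arrays there are 10 splits, too few for a share under 0.05. In stomach the real split gave 1, 254 and 2306 features for aging against normal, codonopsis against aging and codonopsis against normal, and 1 of 10 splits gave as many each time, with 0, 0 and 1 as the highest other. In intestine, 2 features passed between aging and normal, as in 2 of 10 splits with a highest other of 2. Between codonopsis and aging limma called 0 (2966 at an unadjusted p under 0.05), which all 10 splits reached, with up to 4. Between codonopsis and normal intestine 2 passed and 3 of 10 splits gave as many, 1 of them 1183: codonopsis replicates 1 and 3 with normal replicate 3 against the others. That split points to a structure of the samples. For sex 4 of 81 splits in stomach gave at least the 1 real feature, with up to 19, and 2 of 100 in intestine gave at least 10, with up to 889. Both shares lie under 0.05. The splits are too many to keep the real number of males in each group, so they are not like the real one and cannot exclude chance. The larger splits point to a structure of the samples. Between the organs 1 of 100 splits gave 16341, the real one, against 9062 at most otherwise, so chance is excluded.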
